A study of Mus musculus with 10 samples.

How the data were processed

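RNA-seq of Flk1-sorted WT and Ldb1 KO cells gave a deposited table of raw read counts per Ensembl gene for 8 libraries, 4 per genotype, per the file headers. The embryoid body day of the RNA libraries is not given in the sources used here. ChIP-seq of Flk1-sorted cells from day 4 embryoid bodies gave a deposited peak list. It holds, per the file headers, each peak's position, its highest coverage (signal) in the ChIP and in the control library, and an adjusted p-value. The submitters' processing notes name the genome build mm9 and DESeq. The aligner, the counting tool, the strand setting, the annotation release, the peak caller and any scaling of the control coverage are not given in the sources used here. The count table holds 21868 genes, of which 20362 were paired with a symbol. A RefSeq gene table of assembly GRCm38.p6 placed 19332 of them on a chromosome, and it was used for names, chromosome membership, gene overlap and neighbour order alone. Tested on the peak list, no peak has a ChIP coverage under 20 or an adjusted p above 0.00998, and each pair of coverages has 1 p-value, so the authors' list was limited by both values. Whether peak starts count from 0 or 1 is not given in the sources used here.

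Before averaging, the counts of each pair of libraries were compared by a chi-square statistic per gene over genes with at least 20 reads in the pair, where a mean of 1 is sampling noise. The 4 pairs formed by libraries 1 and 2 and by libraries 3 and 4 within a genotype had means of 1.065 to 1.101. The other 8 pairs within a genotype had means of 12.764 to 28.465, and the 16 pairs across genotypes had 30.85 to 45.22. The counts of libraries 1 and 2 and of 3 and 4 were therefore summed, giving 2 samples per genotype, a change from the fit of 8 separate libraries chosen before the data were examined. Total counts per sample were 23182551 and 26221496 for WT A and B and 22674679 and 26775787 for KO A and B. Total counts per library were 11258493 to 13483294. A comparison of a single value between 2 and 2 samples cannot give an exact permutation p below 0.333, so the p-values come from models across all genes.

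Counts were filtered with filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test (robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene levels are counts per 1000000 (CPM) after TMM with mean and SD over samples. Gene lists fixed before the data were examined (20 lists, 395 entries, 380 matched to a symbol of the table) were tested with camera of limma 3.58.1. Camera used log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 19 lists with at least 5 tested members. Camera with an estimated correlation and fry were alternatives. Ratios of genes with 3 or fewer KO reads were scaled to total counts with exact binomial 95% intervals, and a count of 0 was given a floor of 3 counts over the KO group. Chromosome medians used genes with a mean log2 CPM above 3.

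Named genes followed a rule set before the data were examined. It took Ldb1, then up to 12 genes with the most negative and 12 with the most positive log2 fold change among genes past the test with a mean of at least 5 CPM and no overlap between WT and KO libraries. Predicted genes and genes without a symbol were passed over. It also took up to 4 members of each list past the test with at least 1 CPM and the 2 most abundant members that did not pass, and the 10 peaks with the smallest adjusted p. Genes named outside it are marked in the text.

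The edgeR script was tested on simulated data with the real gene means and depths for KO against WT, in 3 runs of 16785 genes. Each gene was given the dispersion of the fitted trend, and 200 changed genes per run were drawn from genes above a minimum of expected reads. It recovered 49.3% of 2-fold, 92.7% of 4-fold, 100% of 8-fold and 100% of 16-fold changes, with at most 8 false calls. With no changed gene it made 0 false calls on 4 samples. It made 1049 to 1269 when each simulated sample was divided into libraries treated as 8 replicates. These rates hold for genes whose spread follows the trend, and real genes with a wider spread can be missed. For example, H19 was 12.3-fold lower in KO and did not pass (edgeR adjusted p = 0.0967).

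Alternatives were RLE, upper quartile and library size scaling, DESeq2 1.42.0, limma-voom, no filter or a stricter filter on low counts, an adjusted p of 0.01, a test against a 1.5-fold change, a replicate block, and leaving out each library. Added after seeing the data were leaving out each sample, fitting 8 libraries separately with or without a block, removing each chromosome's median, and leaving out genes of chromosomes 8 and 11. Peaks were described with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, with Wilson intervals for shares, and figures were drawn with matplotlib 3.10.9. The planned tests of changed genes and list genes against Ldb1 peaks were not run, since they need an annotation of the mm9 build, which was not used here.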

Results

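The series profiled mouse cells sorted for Flk1, the receptor encoded by Kdr that marks the early common progenitors of blood and endothelium. The cells came from embryoid bodies, aggregates in which embryonic stem (ES) cells differentiate, and are called blast colony-forming or hemangioblast-equivalent cells in the labels. RNA-seq compared cells with an intact Ldb1 gene (WT) with cells lacking it on both alleles (KO). Ldb1 is an adaptor protein that joins LIM-domain and other transcription factors into complexes. The labels give 4 RNA libraries per genotype, with total counts of 11494938, 11687613, 13006763 and 13214733 for WT 1 to 4 and 11258493, 11416186, 13292493 and 13483294 for KO 1 to 4. Libraries 1 and 2 of each genotype differed by little more than sampling noise, as did libraries 3 and 4, so each pair was counted as 1 sample. This left sample A (libraries 1 and 2) and sample B (libraries 3 and 4) in each genotype, n = 2, with 22674679 to 26775787 counts per sample. Nothing in the labels says that A and B came from separate cultures, so p-values measure the spread between these samples. In KO that spread may be technical. In WT, sample B differed from sample A by a median log2 of 2.54 over primitive streak genes and -2.36 over pluripotency genes. These opposite shifts argue against a purely technical spread in WT. A chromatin immunoprecipitation (ChIP) library with an Ldb1 antibody and a control library without antibody, both from day 4 embryoid bodies, gave a list of 4252 peaks. For the RNA libraries the day is not given, so they may be of another stage.

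The targeted gene was examined first. Ldb1 (ENSMUSG00000025223) transcripts were present in every library. In normalised counts per 1000000 (CPM) the WT libraries stood at 104.3, 106.1, 110.3 and 116.4 and the KO libraries at 95.8, 96.6, 79.1 and 79.8. The KO level was lower by a log2 fold change of -0.31 (SE 0.15), which did not pass the edgeR test (adjusted p = 0.410). The structure of the knockout allele is not given in the sources used here. Reads from exons outside a deleted part check nothing, so these counts neither bear out nor contradict the genotype labels.

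The comparison of KO with WT asked which genes depend on Ldb1 in these progenitors. Each genotype has only its own cells. For every gene and list below, an effect of Ldb1 loss therefore cannot be told apart from another difference between the cell lines. Genes of early blood formation were among those that fell furthest in the KO samples. Plek, which encodes the platelet and leukocyte protein pleckstrin, fell from 66.9 ± 2.83 to 0.952 ± 0.242 CPM (SD, n = 2 per genotype; log2 fold change -6.13, SE 0.23, edgeR adjusted p = 0.00539). Itga2b, the integrin CD41 of early blood progenitors and megakaryocytes, fell from 54.99 ± 2.502 to 3.06 ± 0.567 CPM (log2 fold change -4.17, SE 0.20, adjusted p = 0.0102). The transcriptional repressor gene Gfi1b and the erythroid and megakaryocytic factor gene Nfe2 fell with log2 fold changes of -4.61 (SE 0.35) and -4.34 (SE 0.36). Among genes that rose, Col1a2, a chain of type I collagen, went from 77.3 ± 0.768 to 704 ± 252 CPM (log2 fold change 3.19, SE 0.28, adjusted p = 0.0493).

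Of 16785 genes tested, 31 passed an adjusted p of 0.05, 21 lower and 10 higher in KO. The other lowered genes included the imprinted genes Mest, at 713 ± 86.4 CPM in WT and 36.0 ± 3.75 CPM in KO (log2 fold change -4.31, SE 0.17, adjusted p = 0.00539), and Plagl1 (-2.81, SE 0.24). Fermt3, which encodes the integrin activator kindlin-3 of blood cells, had a log2 fold change of -3.19 (SE 0.31). The Y-linked genes Eif2s3y (-5.58, SE 0.38) and Uty (-2.71, SE 0.25), the X-linked genes Nxf3 (-3.63, SE 0.25) and Pof1b (-2.93, SE 0.27), the small GTPase gene Rnd2 (-2.04, SE 0.18), the leukaemia inhibitory factor receptor gene Lifr (-1.88, SE 0.18) and Ctla2b (-1.76, SE 0.16) also fell. Ctla2b and its near-identical neighbour Ctla2a may share reads. Copg2 also passed (-1.58, SE 0.14), but its gene model overlaps that of Mest and strand use in counting is not stated, so its value is uncertain; like Ctla2a it was named after its value was seen. Beside Col1a2, the raised genes were Cdkn1c, an imprinted inhibitor of the cell cycle (2.93, SE 0.27), the collagen gene Col5a2 (1.96, SE 0.19), the macrophage growth factor gene Csf1 (1.94, SE 0.19), the tight-junction genes Cldn3 (1.70, SE 0.15) and Cgn (1.29, SE 0.13), the non-muscle myosin gene Myh9 (1.503, SE 0.12), the pro-apoptotic gene Bmf (1.42, SE 0.13) and the intermediate filament gene Nes (1.29, SE 0.13). Vtcn1 completed them (3.22, SE 0.32). Vtcn1 and the lowered opioid precursor gene Pdyn (-4.92, SE 0.44) lay below the mean of 5 CPM set for naming and were named after their values were seen.

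**Figure D1:**
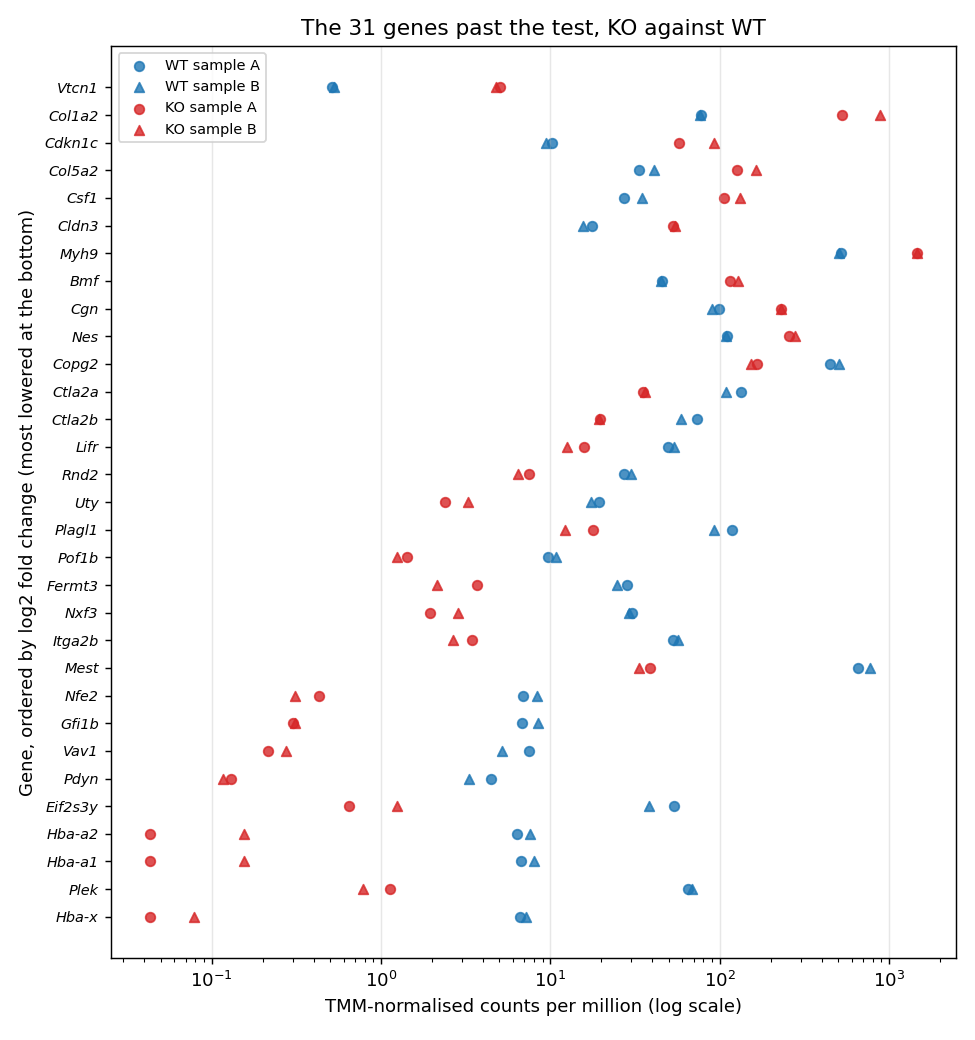
TMM-normalised CPM on a log axis for the 31 genes past the edgeR test, 1 row per gene ordered by log2 fold change, with circles for sample A and triangles for sample B of WT (blue) and KO (red). Plek stands at 64.9 and 68.9 in WT against 1.12 and 0.780 in KO.

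The test was edgeR's quasi-likelihood test, and 2597 genes (1319 lower, 1278 higher) had an unadjusted p under 0.05 against 839.2 expected by chance. The count of 31 depended on the tool and the samples: DESeq2 called 1168 genes, 31 of them shared, and limma-voom called 3, while edgeR without a filter on low counts called 151 and with a filter of 1 CPM in at least 2 samples called 5. Leaving out 1 sample gave 1537 genes without WT sample A, 1674 without WT sample B, and 0 without KO sample A or without KO sample B, where 1704 and 1106 genes had an unadjusted edgeR p under 0.05. Among single libraries, the 10 higher genes became 16 without WT library 4 and 6 without KO library 2. With each chromosome's median difference removed, 22 genes passed, 19 lower and 3 higher (13.6% higher against 32.3%), while at an unadjusted p under 0.05 the balance moved the other way, to 945 lower and 1164 higher.

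The haematopoietic transcription factors stood lower in KO as a group. Of the 23 measured members, Gfi1b and Nfe2 fell over all genes tested and the other 21 did not pass, while 13 fell and 0 rose when p was adjusted over the list alone. Of the most abundant members that did not pass over all genes, Tal1, a factor required for blood specification, stood at 61.2 ± 17.8 CPM in WT and 28.4 ± 11.9 CPM in KO (log2 fold change -1.11, SE 0.37, adjusted p = 0.265), and Etv6 at -0.21 (SE 0.15). Spi1 (-4.22, SE 0.48), Gata1 (-2.02, SE 0.31), Gata2 (-1.39, SE 0.21) and Lmo2 (-1.40, SE 0.38), named after their values were seen, were among the 13. The median log2 fold change was -1.40, and camera with a preset correlation of 0.01 gave an adjusted p of 3.3e-11 over 19 lists. The call was lost with an adjusted p = 0.644 with an estimated correlation.

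Globin genes were at or near 0 in KO. The embryonic alpha-like globin gene Hba-x had 343 reads in WT and 3 in KO, a depth-scaled ratio of 114.4 with a 95% exact counting interval from 38.8 to 557.7, and Hba-a1 and Hba-a2, near-identical copies whose reads may be split between them, fell with log2 fold changes of -6.11 (SE 0.52) and -6.02 (SE 0.52). These 3 were the erythroid genes that passed over all genes, of 21 measured, and 9 fell and 0 rose adjusted over the list alone. The embryonic beta-like globin gene Hbb-bh1 had 771 reads in WT and 0 in KO, at least 257.2-fold lower when 3 counts over the KO group are taken as the floor, yet its WT samples differed and it did not pass (adjusted p = 0.0719). Hbb-bh1 was named after its value was seen, and intervals and floors cover counting error only. Tfrc, the transferrin receptor gene, was the most abundant member and stood at 160 ± 29.8 CPM in WT and 129 ± 1.05 CPM in KO (log2 fold change -0.31, SE 0.17, adjusted p = 0.461), and the mitochondrial iron carrier gene Slc25a37 had a log2 fold change of 0.11 (SE 0.19). The list's median was -0.63, also with Hbb-bh1 at its bound. Camera gave an adjusted p of 2.6e-09, against an adjusted p = 0.221 with an estimated correlation.

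Early blood, megakaryocyte and myeloid genes also stood lower in KO as a group. Plek, Itga2b and Vav1, a blood-cell signalling gene with a log2 fold change of -4.65 (SE 0.41), fell over all genes, the other 16 of 19 measured members did not pass, and 9 fell and 0 rose adjusted over the list alone. The receptor gene Kit (130.5 ± 44.6 CPM in WT, 75.9 ± 27.0 CPM in KO, log2 fold change -0.78, SE 0.36) and Cd34 (-0.73, SE 0.46) did not pass. The median was -1.25, also with the megakaryocyte gene Gp5, at 32 reads in WT and 0 in KO, set to its bound of at least 10.7-fold lower. Camera gave an adjusted p of 6.11e-11, against an adjusted p = 0.221 with an estimated correlation. Chromosome 11, whose genes as a whole stood at a median of -0.47 in KO, carries 2 of the 23 transcription factors, 4 of the 21 erythroid genes and 5 of these 19. Without genes of chromosomes 8 and 11 the 3 medians were -1.30, -0.40 and -0.92, with camera adjusted p of 6.02e-10, 1.34e-05 and 2.09e-07.

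By edgeR no endothelial gene passed over all genes or adjusted over the list alone, where 8 lower and 0 higher had an unadjusted p under 0.05, though 30 of 32 measured members lay below 0. Pecam1, an endothelial and blood adhesion molecule gene, stood at 224 ± 132 CPM in WT and 54.9 ± 21.3 CPM in KO (log2 fold change -2.03, SE 0.55, adjusted p = 0.215). Kdr itself, which encodes the marker used for the sort and is therefore no finding of its own, stood at 440 and 605 CPM in WT samples A and B and 236 and 78.6 CPM in KO samples A and B (log2 fold change -1.73, SE 0.59, adjusted p = 0.289). The median was -0.90 and camera gave an adjusted p of 8.04e-07, against an adjusted p = 0.691 with an estimated correlation. Between samples of one genotype the list differed about as much, with medians of sample B minus sample A of -0.56 in WT and -0.93 in KO. Cd34, Erg and Fli1 belong to this list and to a blood list. By DESeq2, 4 of the members were lower and 0 higher.

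Smooth muscle and mesenchyme genes stood higher in KO. Col1a2 rose over all genes, the other 15 of 16 measured members did not pass, and 11 rose and 0 fell adjusted over the list alone. The actin-binding tropomyosin gene Tpm1, among those 11, went from 633 ± 177 to 1362 ± 342 CPM (log2 fold change 1.11, SE 0.27, adjusted p = 0.168 over all genes), whereas fibronectin, Fn1, stood at 0.19 (SE 0.19). Des, Tagln and Acta2, muscle cytoskeleton genes named after their values were seen, had log2 fold changes of 1.38 (SE 0.15), 1.69 (SE 0.42) and 1.08 (SE 0.35). The median was 1.03 and camera gave an adjusted p of 1.25e-07, against an adjusted p = 0.691 with an estimated correlation. Within a genotype, the list's medians of sample B minus sample A were 0.19 in WT and 0.66 in KO.

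**Figure D2:**
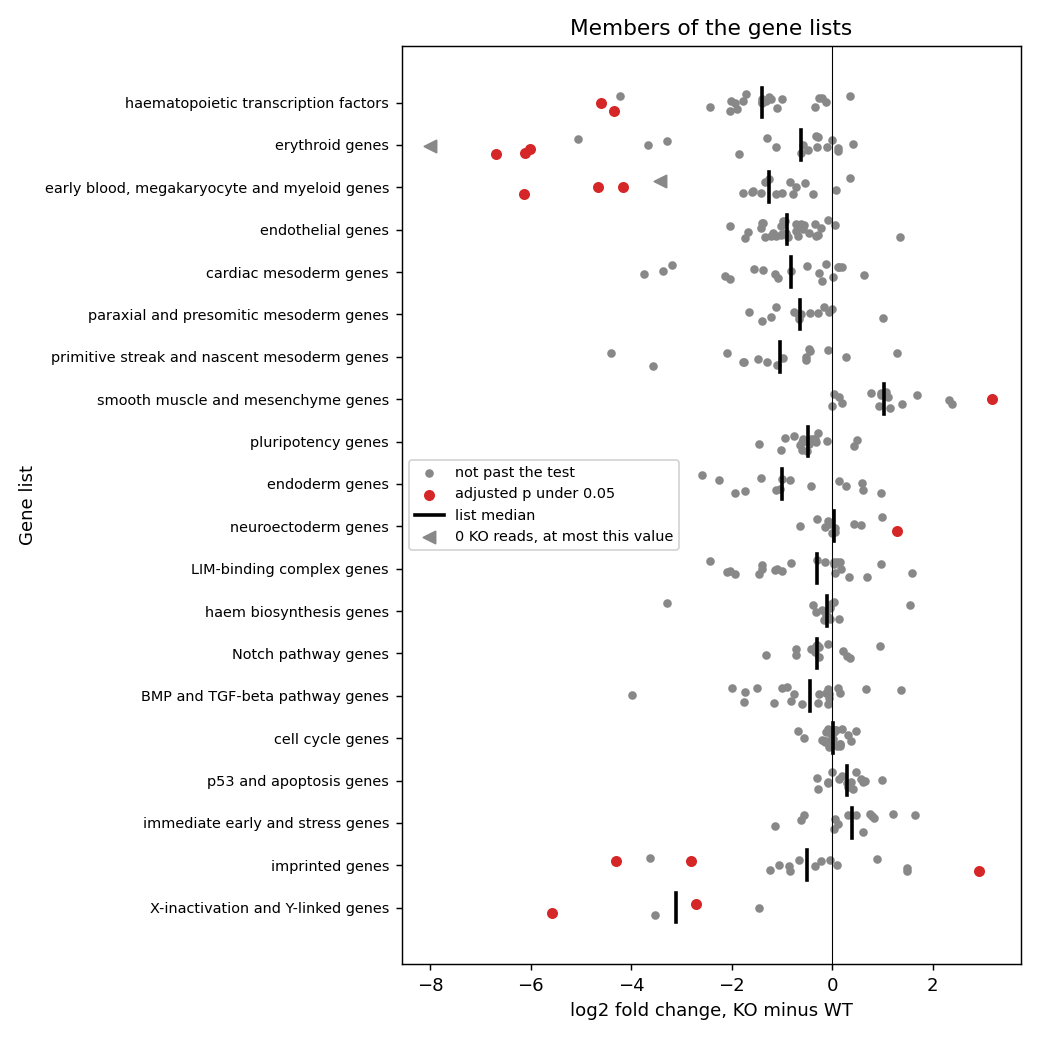
Log2 fold change of KO minus WT (horizontal axis) for each measured member of the 20 gene lists (rows), with grey points for members that did not pass, red points for an adjusted p under 0.05, triangles at the bound for Hbb-bh1 and Gp5 (0 KO reads) and a black bar at each list's median. The medians of the haematopoietic transcription factors (-1.40) and early blood genes (-1.25) lie left of 0 and that of smooth muscle and mesenchyme genes (1.03) right of it.

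These 5 lists were those past camera among 19 tested, and with an estimated correlation 0 passed, where 2 had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance, passed 2, the erythroid and the early blood lists, at an adjusted p of 0.0209 each. Its mixed form, which takes changes in either direction, passed these 2 and the haematopoietic factors (adjusted p = 0.0125). The mixed form also passed the imprinted (0.00567), neuroectoderm (0.00564), cell cycle (0.0162) and haem biosynthesis (0.031) lists. The number past camera was 12 without WT sample A, 9 without WT sample B, 9 without KO sample A and 5 without KO sample B.

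Genes of LIM-binding complexes, in which Ldb1 acts, moved in both directions. Of 23 measured members 0 passed over all genes by edgeR, where 8 lower and 3 higher had an unadjusted p under 0.05 and DESeq2 called 6 lower and 3 higher, while 5 fell and 3 rose adjusted over the list alone. The 5 were Gata1, Gata2, Cbfa2t3, Lyl1 and Lmo2, which all belong to the haematopoietic factors too. The 3 were Ssbp2 (1.60, SE 0.18), Lmo4 (0.96, SE 0.24) and Ssbp3, at 171 ± 37.9 CPM in WT and 276 ± 28.1 CPM in KO (0.69, SE 0.19, adjusted p = 0.179), and apart from Ssbp3 these 8 were named after their values were seen. The demethylase gene Kdm1a stood at 0.16 (SE 0.12). The list's median was -0.31 and camera gave an adjusted p of 0.109, against 0.00943 without KO sample A. Without genes of chromosomes 8 and 11 the median was -0.14 (camera adjusted p = 0.209).

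Imprinted genes also moved in both directions. Of 16 measured, Mest and Plagl1 fell and Cdkn1c rose over all genes, and 5 fell and 4 rose adjusted over the list alone. H19, an imprinted noncoding RNA, stood at 1178 and 2320 CPM in WT and 113 and 172 CPM in KO (log2 fold change -3.62, SE 0.44, adjusted p = 0.0967), and its growth factor neighbour Igf2 at 487 ± 278 CPM in WT and 1362 ± 97.9 CPM in KO (1.48, SE 0.43, adjusted p = 0.229). The median was -0.50 and camera gave an adjusted p of 0.12, against 0.0105 without WT sample A. All 4 measured Y-linked genes fell adjusted over the list alone, with Kdm5d at -3.52 (SE 0.36, adjusted p = 0.0529 over all genes) and Ddx3y at -1.46 (SE 0.17, adjusted p = 0.0683) beside Eif2s3y and Uty. Each has an X-linked relative that may share reads, and a list of 4 got no camera test.

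In neuroectoderm genes Nes rose and the other 11 of 12 did not pass, with Otx2 at 0.05 (SE 0.20) and Zic2 at 0.57 (SE 0.19), and 1 rose and 0 fell adjusted over the list alone (median 0.03, camera adjusted p = 0.189). By edgeR, no member of the following lists passed over all genes. Of 14 haem biosynthesis and iron transport genes, 1 fell and 1 rose adjusted over the list alone, with the iron exporter gene Slc40a1 at 1.55 (SE 0.28) and Cpox at -0.09 (SE 0.14; median -0.11, camera adjusted p = 0.263). The same numbers had an unadjusted p under 0.05 and were called by DESeq2. Of 16 p53 and apoptosis genes, 1 rose and 0 fell adjusted over the list alone, with Ccng1 at -0.08 (SE 0.26) and Trp53inp1 at 0.31 (SE 0.18; median 0.30, camera adjusted p = 0.0622), while 3 higher and 0 lower had an unadjusted p under 0.05 and DESeq2 called 2 higher. Of 15 endoderm genes, 1 fell and 1 rose adjusted over the list alone, with the endocytic receptor gene Lrp2 at 0.98 (SE 0.16) and Dab2 at 0.60 (SE 0.21; median -1.0, camera adjusted p = 0.12), while 2 lower and 2 higher had an unadjusted p under 0.05 and DESeq2 called 1 lower and 1 higher. None of 24 cell cycle, 15 Notch pathway, 22 BMP and TGF-beta pathway or 14 immediate early genes passed by edgeR adjusted over the list alone. In these 4 lists, in that order, 2, 2, 2 and 0 lower and 2, 1, 1 and 2 higher genes had an unadjusted p under 0.05, and DESeq2 over all genes called 2, 1, 1 and 0 lower and 0, 1, 1 and 0 higher. The medians were, in the same order, 0.01, -0.29, -0.44 and 0.39 and the camera adjusted p values 0.956, 0.266, 0.125 and 0.125. Camera passed more of these lists when 1 sample was left out. Without WT sample A the endoderm (0.0497) and BMP (2.85e-06) lists passed, without WT sample B the p53 (0.0102) and immediate early (0.0106) lists, and without KO sample A the endoderm (0.000327), p53 (0.00125) and immediate early (0.000646) lists. The medians of sample B minus sample A were 0.34 in WT and 0.31 in KO for the p53 list and 0.65 and 0.85 for the immediate early list, no smaller than the medians of KO minus WT. The immediate early median was 0.21 (camera adjusted p = 0.303) without genes of chromosomes 8 and 11. For the cell cycle list the median was above 0 and the mean (-0.01) and the test's direction below it. Their most abundant members were Top2a (-0.67, SE 0.13, on chromosome 11) and Mki67 (-0.13, SE 0.28), Notch3 (0.36, SE 0.30) and Rbpj (0.29, SE 0.24), Smad5 (0.16, SE 0.15) and Smad1 (-0.26, SE 0.28), and Btg2 (0.06, SE 0.29) and Jun (0.04, SE 0.37).

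The WT samples differed from each other in mesoderm and pluripotency genes more than the KO samples did. Between WT samples A and B 433 genes differed more than 4-fold, against 38 between the KO samples. Eomes, a factor of nascent mesoderm, stood at 9.65 and 116 CPM in WT A and B and at 27.8 and 8.94 CPM in KO A and B, while the pluripotency gene Dppa5a stood at 630 and 75.03 CPM in WT A and B and at 209 and 356 CPM in KO A and B. The median log2 difference of WT B from WT A was 2.54 for primitive streak genes and -2.36 for pluripotency genes. Against KO, 0 of 16 primitive streak genes passed by edgeR, over all genes or adjusted over the list alone, where 1 had an unadjusted p under 0.05 and DESeq2 called 1, each higher in KO against the direction of the median (-1.04, camera adjusted p = 0.444). Of 18 pluripotency genes 0 passed, where 3 had an unadjusted p under 0.05 and DESeq2 called 3, all lower (median -0.48, camera adjusted p = 0.441). Both lists turned round with the sample left out: pluripotency genes stood higher in KO without WT sample A (camera adjusted p = 6.98e-06) and lower without WT sample B (5.49e-08), while primitive streak genes stood lower without WT sample A (1.14e-05) and higher without WT sample B (0.0125). Pou5f1 stood at 0.50 (SE 0.61) and Fgf4 at -0.46 (SE 1.02). None of 19 cardiac mesoderm genes (median -0.82, camera adjusted p = 0.12) or 14 paraxial mesoderm genes (median -0.65, camera adjusted p = 0.0622) passed by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 cardiac and 2 paraxial genes, 1 lower and 1 higher, and DESeq2 called 0 and 1, the latter higher. Both lists passed camera without WT sample A (5.25e-08 and 0.00119). Without genes of chromosomes 8 and 11, which hold 5 of the 19, the cardiac median was -0.39 (camera adjusted p = 0.244). Actc1 stood at 0.12 (SE 0.19), Myh7 at 0.20 (SE 0.53), Pdgfra at -1.66 (SE 0.78) and Lfng at 1.02 (SE 0.26).

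Expression differed between the genotypes along whole chromosomes. The 890 expressed genes of chromosome 11 had a median log2 fold change of -0.47, with 90.3% of them below 0, and the 597 of chromosome 8 had a median of 0.25, with 15.2% below 0. The other autosomes had medians between -0.002 and 0.051. The chromosome 11 median lay between -0.50 and -0.42 in each of the 4 pairings of a KO with a WT sample, and was 0.002 between the WT samples. Camera gave adjusted p values of 6.25e-29 for chromosome 11 and 1.76e-09 for chromosome 8, against an adjusted p = 0.168 and an adjusted p = 0.495 with an estimated correlation. Of the 31 genes past the test, 6 lie on chromosome 11, Plek, Itga2b, Hba-x, Hba-a1, Hba-a2 and Rnd2, all lower in KO.

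**Figure D3:**
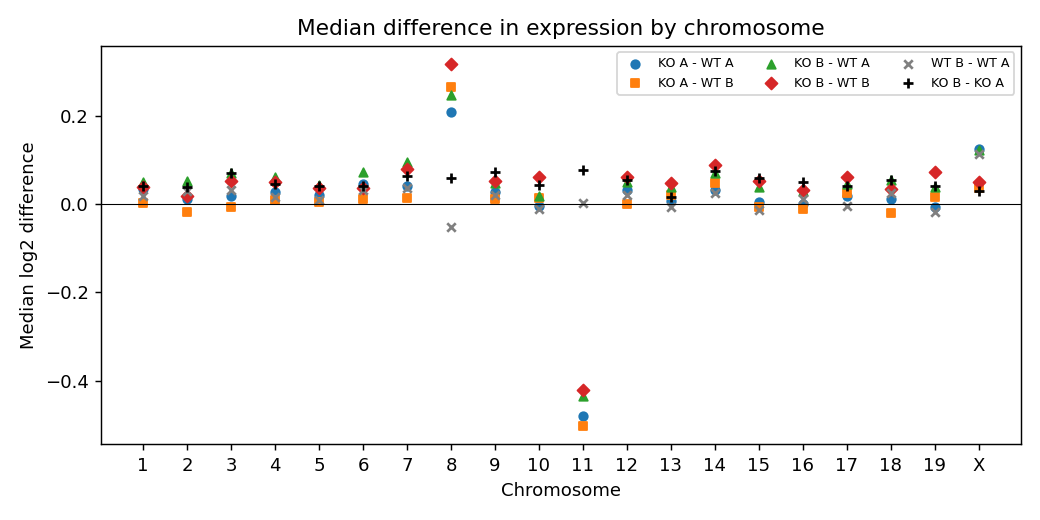
Median log2 difference in expression (vertical axis) of expressed genes on each autosome and the X chromosome (horizontal axis), with 1 symbol for each of the 4 KO minus WT sample pairings, crosses for WT B minus WT A and plus signs for KO B minus KO A. Chromosome 11 lies at -0.50 to -0.42 and chromosome 8 at 0.21 to 0.32 in the 4 pairings.

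The ChIP arm asked where Ldb1 binds the genome in these cells. The strongest of the 4252 peaks by the authors' adjusted p lay on chromosome 4, from 114768020 to 114768970 (mm9), with a highest coverage of 243 reads in the ChIP library and 11 in the control (3.11e-54). The next lay on chromosome 15 from 99494860 to 99495800 (204 against 9) and on chromosome 8 from 122893570 to 122894460 (206 against 12). Of the 10 strongest peaks 4 lay on chromosome 8, the others of them starting at 87224880, 122895400 and 74791978. The remaining peaks of the 10 started at 50840550 and 136805850 on chromosome 6, at 172860160 on chromosome 2 and at 107884778 on chromosome 9. Chromosome 11 held 912 peaks, 21.5% of all (95% Wilson interval 20.2% to 22.7%), and chromosome 8 held 340, or 8.0% (7.22% to 8.85%). Scaled to gene content, chromosome 11 carried 56.7 peaks per 100 protein-coding genes and chromosome 8 carried 32.6, against 10.3 to 23.7 on the other autosomes and 2.28 on the X chromosome.

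Most peaks were of modest height. The median coverage was 24 reads in the ChIP library and 5 in the control, a median ratio of 5.6, and 3187 peaks (74.95%) lay below 30 reads, while 54 reached 100. Median width was 648 bp (183 to 2970 bp), and 487 peaks (11.5%) lay within 5 kb of another. Among the 425 peaks with the smallest adjusted p the share on chromosome 11 was 13.7%. Peaks with a ChIP coverage of at least 40 numbered 4.47 per 100 protein-coding genes on chromosome 11 and 4.60 on chromosome 8, against 1.43 to 3.48 on the other autosomes. With 1 library on each side there was no replicate check of any peak. An annotation of the mm9 build was not used here, so no peak was assigned to a gene and the overlap of bound with changed genes was not analysed here.

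**Figure D4:**
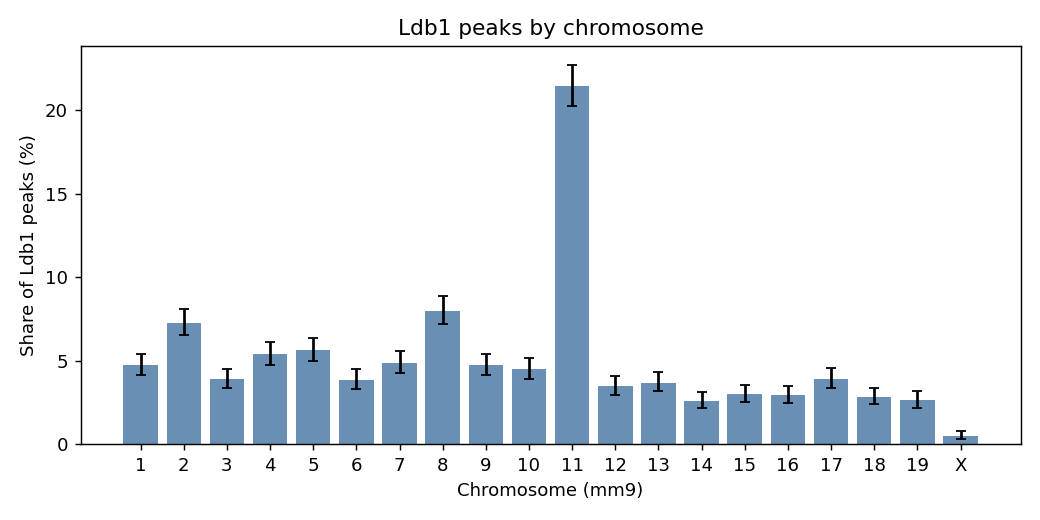
Share of the 4252 Ldb1 peaks (vertical axis, percent) on each autosome and the X chromosome (horizontal axis), with bars for the share and lines for its 95% Wilson interval. Chromosome 11 holds 21.5% and each of the others at most 8.0%.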

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

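Settings added after seeing the data are the samples left out, the 8-library fits, the removal of chromosome medians and the exclusion of chromosomes 8 and 11. The number of changed genes (31, 21 lower and 10 higher) stayed within 1.5 times under RLE, upper quartile and library size scaling (25 to 30). Without any 1 library the total (22 to 40) and the lower genes (16 to 25) did so too, but the higher genes went from 6 without KO library 2 to 16 without WT library 4. Leaving out 1 library lowers the depth of a sample and removes no sample, so it says nothing on dependence on samples. DESeq2 called 1168 (596 lower, 572 higher), limma-voom 3 (3 and 0), no filter 151 (79 and 72) and the stricter filter 5 (5 and 0). An adjusted p of 0.01 left 2 (2 and 0) and a test against 1.5-fold 5 (5 and 0). Most of the 31 genes have adjusted p just under 0.05. A limit or filter that moves that adjusted p slightly ends many calls, but the cause of each shift was not tested. All 31 were among the calls of DESeq2 and of the unfiltered test.

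The replicate block, which treats A and B as blocks across genotypes, left 5 genes (5 lower, 0 higher; 1204 higher genes at an unadjusted p under 0.05), 4 of them among the 31, and 7 lists, with p53 (0.0232) and immediate early genes (0.028) added. The numbers share no stated culture or day, and the deviations of B from A correlated at -0.081 between genotypes across genes, which are not independent replicates, so this loss is not read as a weaker effect. Leaving out WT sample A gave 1537 genes (769 lower, 768 higher) and 12 lists, and leaving out WT sample B 1674 (989 and 685) and 9 lists, all 31 included each time. Leaving out KO sample A gave 0 (0 and 0) and 9 lists, and KO sample B 0 (0 and 0) and 5 lists; the lone sample is then assumed to vary like the pair. By edgeR 1704 and 1106 genes had an unadjusted p under 0.05 in these fits and no other tool was run. Without WT sample A, Fgf4 (1.83, adjusted p = 0.000182), Dppa5a (1.90, adjusted p = 0.0301) and the pluripotency list (camera adjusted p = 6.98e-06) turned to higher in KO, and without WT sample B the primitive streak list did (0.0125); the different levels of these genes in WT samples A and B show the cause. Over the fits without a library or sample, Fgf4 ranged from -1.31 to 1.83, Dppa5a from -1.15 to 1.90, and camera adjusted p from 1.14e-05 to 0.919 for the primitive streak and from 5.49e-08 to 0.855 for the pluripotency list. The 8 libraries as separate replicates gave 3860 (1892 and 1968) and Ldb1 past the test at -0.31 (adjusted p = 0.0234), and with a replicate block 3410 (1635 and 1775), with Ldb1 at adjusted p = 0.0675; libraries of 1 sample carry no spread between samples. Ldb1 kept its direction in every setting run, with log2 fold changes of -0.44 to -0.18 and adjusted p of 0.280 to 0.958 outside the 8-library fits.

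Removing chromosome medians left 22 genes (19 lower, 3 higher), all among the 31, with 945 lower and 1164 higher at an unadjusted p under 0.05. Of the 5 lists past camera, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), 2 passed the directional form of fry, and 5 passed without genes of chromosomes 8 and 11. The 2126 peaks with the smallest adjusted p put 23.8% on chromosome 11 and the top 425 put 13.7%, against 21.5% of 4252. Not run were the settings of the tests of peaks against changed genes and list genes. Depth limits Hbb-bh1 and Gp5, with 0 reads in KO.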

Other observations

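The tests of library scaling, of the Y-linked genes, of imprinted genes against the commoner direction and of the peak excess were chosen after the results were seen. The others were set before they were run, but after the pattern they address was seen.

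The median log2 difference of WT sample B from WT sample A was -2.36 over the pluripotency list and 2.54 over the primitive streak list. The single genes given here were chosen after their values were seen. The germ cell gene Dazl stood at 62.2 CPM in WT A and 3.81 CPM in WT B, against 5.53 and 5.97 CPM in the KO samples. Tex14, another germ cell gene, stood at 46.9 and 4.38 CPM in WT A and B. The heart and mesoderm factor gene Hand1 stood at 9.90 and 126 CPM in WT A and B and at 6.87 and 6.36 CPM in KO A and B, and Hand2 at 0.982 and 33.2 CPM in WT A and B. The node and streak gene Cfc1 stood at 1.45 and 58.2 CPM in WT A and B. Of the 433 genes over 4-fold apart, 273 were higher in WT A and 160 in WT B.

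Chromosome 11 genes were lower and chromosome 8 genes higher in KO. Library scaling would move other chromosomes as well, and the autosome farthest from 0 among them had a median of 0.051. A few strong genes would leave most genes in place, yet 91.1% of chromosome 11 genes lay below the median autosomal gene. Copy number of the whole chromosomes in the ES cell lines is a candidate explanation. Of 10 consecutive blocks of genes, the highest median on chromosome 11 was -0.39 and the lowest on chromosome 8 was 0.163. Each lay past a limit set before the blocks were examined, but after the shifts of these chromosomes were seen. An effect of Ldb1 loss along a whole chromosome stays open and was not tested, since each genotype has only its own cells.

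Y-linked and imprinted genes differed between the genotypes. For the Y-linked genes, loss of the Y chromosome from most KO cells is a candidate explanation. The 4 stood at -5.58 (Eif2s3y), -3.52 (Kdm5d), -2.71 (Uty) and -1.46 (Ddx3y). Loss alone would lower them alike, so it does not account for the unequal fall. Reads shared from X-linked relatives could make the fall unequal and were not tested. A KO line that began without a Y chromosome, with reads shared from X-linked relatives, would look alike and was not tested. The imprinted genes did not all follow a change that lowers every paternally and raises every maternally expressed gene, or the reverse. Of 9 genes past the test within the list 2 went against the commoner direction, maternally expressed H19 (-3.62, SE 0.44) and paternally expressed Igf2 (1.48, SE 0.43). These 2 are neighbours and so are not independent exceptions, and the question was chosen after their values were seen. A change at most imprinted genes with this locus apart is not argued against. Genes were sorted by expressed allele alone, so a common gain or loss of DNA methylation at imprinted genes was not tested. Below 0 were 8 of 10 paternally and 3 of 6 maternally expressed genes, and whether a shift on average exists stays open, with class medians -1.18 apart (two-sided exact permutation p = 0.106 over genes, which are not independent replicates). A difference between the ES cell lines and an effect of Ldb1 loss on these genes cannot be told apart, since cells and genotype are confounded.

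Ldb1 peaks were in excess on chromosome 11, at 56.7 per 100 protein-coding genes against 10.3 to 32.6 on the other autosomes, where chromosome 8 is the highest. The excess per gene over every other autosome rests on peaks with a ChIP coverage under 40: for these gene density alone would keep the rate within 8.82 to 28, and chromosome 11 had 52.2. For stronger peaks gene density stays open, since chromosome 11 had 4.47 per 100 genes and chromosome 8 had 4.60, with 1.43 to 3.48 on the rest. Extra copies in the cells of both libraries would raise the control coverage. At weaker peaks of the same ChIP coverage it was 0.89 times as high on chromosome 11 as on other autosomes (bootstrap 95% interval 0.843 to 0.935). At those of 30 to 39, where the peak call limits the control least, it was 0.954 times as high (0.832 to 1.104). The peak call removes regions with a high control, so a rise at weaker peaks may be hidden. The X chromosome, at 0.451 times the autosomes (0.253 to 0.707), shows only that a fall can be seen. The weaker peaks therefore decide nothing on extra copies. At strong peaks, unmatched, the ratio for chromosome 11 was 1.08 (0.881 to 1.29, narrowly under the limit of 1.3). These peaks were selected by the same call, and the limit was chosen after the results were seen, so they do not decide on extra copies either. Extra copies in the cells of both libraries therefore stay open. Copies gained in part of the cells, or in the ChIP cells and not the control's, may also contribute and were not tested, and no biological explanation was tested.

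Of the 3 ways to divide the 4 samples into pairs, 1 called as many genes as the real one, which is the real one itself with 31 by edgeR. The others called 0 at most, with 236 and 400 genes at an unadjusted p under 0.05 and 4 and 17 calls by DESeq2. Each of the others puts 1 WT and 1 KO sample in each group, so the genotype difference widens the spread within groups. Both counts of genes lie below the 839.2 expected by chance, so the 0 calls there do not back the 31. With 3 splits the share cannot fall below 0.05.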
